A study of Mus musculus with 21 samples.

How the data were processed

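Bulk RNA-seq of left ventricle tissue was deposited for 21 libraries from male C57BL/6 mice, 3 biological replicates in each of 7 groups. Per the labels, mice were 8 weeks old at surgery and hearts were taken at week 8 after it. Sham mice had the operation without a constriction, and AB mice had aortic banding, which raises the pressure load on the left ventricle. AB_Implant mice were banded and received a vagus nerve stimulator at week 1 that was never switched on. Stimulated mice were banded and received low-level vagus nerve stimulation (4 µA, 2 Hz) through a cuff on the left cervical vagus, driven by a biodegradable triboelectric nanogenerator, a device that turns motion into current. VNS20_1w, VNS20_2w and VNS20_4w had 20 min daily from weeks 1, 2 and 4, for 7, 6 and 4 weeks. VNS10_1w had 10 min daily from week 1 for 7 weeks. Each library was labelled as a biological replicate, so the p-values below describe spread between mice.

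Per the labels, total RNA with an RNA integrity number above 8 was used, polyadenylated RNA was selected and libraries were sequenced as paired reads on an Illumina instrument. Per the submitters' processing notes, the tools were FastQC 0.11.9, cutadapt 1.11, HISAT2 2.1.0, featureCounts 1.6.0, R 4.0.3 and edgeR 3.32.1, with the mouse build GRCm38. The authors deposited 1 table of 22136 genes by 21 libraries whose name speaks of normalized counts. The deposited values were read as raw counts, because 100% of them were whole numbers and because library totals differed from 11577509 to 19414865 counts. As a test, the number of genes at each count was compared with the numbers at neighbouring counts, since scaling and rounding leave gaps. This unevenness, which is near 1 in unscaled counts, was 0.789 to 1.13 in the libraries as deposited, and 1.94 or more in copies scaled by 5 factors from 0.6 to 1.5 and rounded. The test for raw counts fixed in advance was therefore used, and not the one fixed for normalized values.

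Genes were kept with at least 1 CPM (counts scaled by library total) in at least 3 libraries, which left 12100 genes to test; 4898 of the 22136 genes had 0 counts in every library. Symbols were found for 22041 genes, and lengths, GC content and coordinates came from GENCODE release M21 on GRCm38. Counts were scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, all 21 libraries and 7 groups in 1 model without covariates). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. All adjusted p-values of single genes come from this test unless another tool is named, and standard errors (SE) are on the log2 scale. Group values are mean CPM with the SD of 3 libraries unless another n is given. The counts give no strand, so antisense and overlapping genes cannot be separated, and near-identical copies such as Hspa1a and Hspa1b may share reads.

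There were 13 contrasts and 1 F test over the start weeks. Banding was tested as AB against Sham and AB_Implant against Sham, and the inactive device as AB_Implant against AB. Each stimulated group was tested against AB_Implant and against AB, the mean of the 4 stimulated groups against the mean of AB and AB_Implant, and VNS20_1w against VNS10_1w.

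In total 32 gene lists were fixed, 16 pathways and 16 sets of cell type markers, and the 28 with at least 3 tested members entered the tests. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all in limma 3.58.1, and p-values were adjusted (Benjamini-Hochberg) over the lists of a contrast. Members past the threshold were counted over all genes and adjusted over the list alone. A banding score was planned from the genes called in AB against Sham. That set was empty, so the score took the 100 genes higher and the 100 genes lower in AB with the smallest p, a choice listed in advance as the other way to score. The score is the mean log2 CPM (pseudocount 0.5) of the first set minus that of the second and was compared by two-sided exact permutation tests.

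The named genes followed a rule. They were the 8 largest rises and 8 largest falls among called genes with a symbol of their own (not a clone or predicted gene name), a mean of at least 5 CPM and groups that do not overlap, and up to 4 called members of each list. In comparisons without a call, the 3 genes of the smallest p under the same conditions were taken (without the condition on overlap in the F test), of which the text gives 2 for AB against Sham. Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Col1a1, Col3a1, Postn, Timp1, Chrm2, Adrb1 and Il1b were always taken, and Il6 and Tnf did not pass the filter. The text does not give all of these for every comparison. Other genes are named as chosen after their values were seen. The groups, tests, lists, naming rule and most other settings were fixed before the data were examined.

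The other settings tried were no filter, a mean of at least 5 CPM, DESeq2 size factors, DESeq2 1.42.0, a fit on the compared groups only, the replicate number as a block, limma with sample weights, other pseudocounts for the score, and each library left out in turn. Further settings were chosen after seeing the data. These were the length slope of each library as a covariate, a GC and length offset (smooth trends, mgcv 1.9.3), and leaving out the 3 libraries with a length slope over 0.3. The length slope is the slope of a library's log2 CPM, relative to the mean of all libraries, on log2 transcript length, fitted together with GC content.

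The pipeline was tested on simulated data, with counts drawn for the 12100 genes and 50 genes changed at each fold. For VNS20_1w against AB_Implant, 12% of genes were recovered at a 2-fold, 54% at a 4-fold, 88% at an 8-fold and 94% at a 16-fold change, with 7 unchanged genes among 131 calls. For the 4 stimulated groups together these shares were 64%, 86%, 100% and 100%. The list tests called the raised set and 0 of 20 unchanged sets. The genes of this simulation were drawn independently of each other. It therefore cannot show how often camera with the preset correlation calls unchanged lists of correlated genes. The counts behind these shares also held no differences in length slope, so 7 among 131 does not give the share of false calls in the real libraries. Folds against a group with 0 counts were computed against a floor of 3 counts over the group, and folds against few counts have 95% counting intervals. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No column of the table was left out.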

Results

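Messenger RNA of the left ventricle was measured in 21 mice, 3 in each of 7 groups. The groups were sham surgery (Sham), aortic banding (AB), banding with an implanted vagus nerve stimulator left off (AB_Implant), and 4 banded groups with active stimulation. Of these, 3 received 20 min a day from week 1, 2 or 4 (VNS20_1w, VNS20_2w, VNS20_4w) and 1 received 10 min a day from week 1 (VNS10_1w). All hearts were taken at week 8. Library totals lay between 11577509 and 19414865 counts, and 12100 genes were tested.

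The libraries differed most in how strongly counts depended on transcript length. The first principal component held 48.1% of the variance and followed the length slope of the libraries (n = 21, r = -0.99, Spearman correlation -0.97, permutation p = 1e-05 for both, the smallest that 100000 permutations can give). Without the 2 libraries farthest from the median slope r was again -0.99. Slopes ran from -0.288 to 0.412 log2 CPM per log2 of length. The 3 VNS20_4w libraries lay between -0.288 and -0.235 and the 3 AB_Implant libraries between 0.0315 and 0.235. VNS20_1w replicate 2, VNS20_2w replicate 1 and VNS10_1w replicate 2 lay above 0.3. The median slope was -0.185 in the 12 stimulated and 0.0658 in the 9 other libraries, and 27.3% of the slope's variance lay between groups. The 13 mitochondrial genes took 34.4% to 55.3% of the counts.

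**Figure D1:**
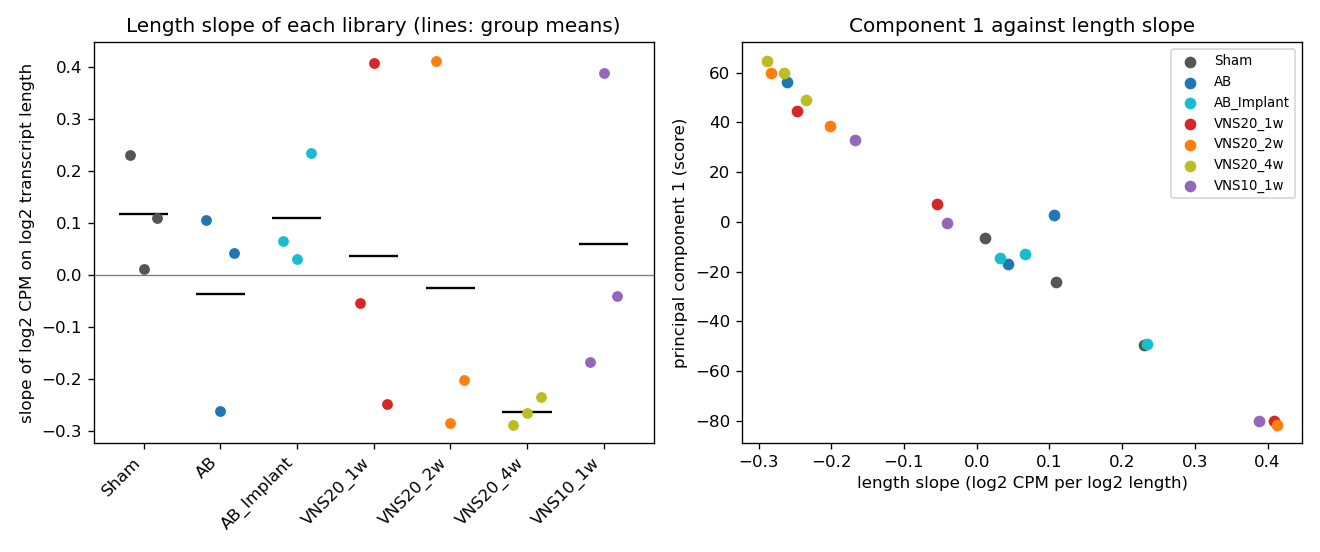
Length slope of each library by group (left; dots are libraries, lines are group means, in log2 CPM per log2 of transcript length), and first principal component score against length slope (right). The 3 libraries above 0.3 belong to 3 different stimulated groups, and the 3 VNS20_4w libraries all lie at or below -0.235.

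AB against Sham asked what 8 weeks of pressure overload changed. Known markers of cardiac hypertrophy had higher means in AB, but 0 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Acta1, skeletal alpha actin, was 374 ± 68.8 CPM (SD, n = 3) in Sham and 3294 ± 2573 in AB (log2 fold change 3.14 ± 0.91 SE, adjusted p = 0.836). Nppb, brain natriuretic peptide, was 122 ± 91.8 and 826 ± 625 CPM (2.76 ± 0.81, adjusted p = 0.836), and Nppa, atrial natriuretic peptide, 222 ± 121 and 916 ± 548 CPM (2.05 ± 0.77, adjusted p = 0.836). Among the genes with the smallest p by the naming rule, none past the threshold, were Cebpb, a transcription factor of stress and inflammation (4.05 ± 0.76, adjusted p = 0.258), and Myot, a sarcomeric Z-disc protein (1.65 ± 0.37, adjusted p = 0.641). Myh6, the adult myosin heavy chain (-0.09 ± 0.23, adjusted p = 0.909), and Atp2a2, the calcium pump of the sarcoplasmic reticulum (-0.61 ± 0.30, adjusted p = 0.836), did not pass either. The remaining genes of the fixed set (Myh7, Col1a1, Col3a1, Postn, Timp1, Chrm2, Adrb1, Il1b) lay between -1.63 for Il1b and 1.25 for Postn, with adjusted p of at least 0.836.

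Among the lists, 4 of 17 fetal and hypertrophy genes were higher in AB when adjusted over the list alone and 0 over all genes (median log2 fold change 0.91, camera adjusted p = 2.94e-07, adjusted p = 0.414 with an estimated correlation). All 5 tested red blood cell markers were higher adjusted over the list alone, 0 over all genes (median 1.4, camera adjusted p = 9.02e-06, adjusted p = 0.414 with an estimated correlation). Of the 28 lists, 10 were called by camera and 0 with an estimated correlation or by fry. At an unadjusted p under 0.05 there were 604 genes, the smallest adjusted p was 0.139, DESeq2 called 11 genes, and 7 were called without Sham replicate 3. With the length slope as a covariate 4 genes were called, and 3 without the 3 libraries of the steepest slopes.

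AB_Implant against Sham compared the second unstimulated banded group with the same controls, and here 34 genes were called, 28 higher and 6 lower. The rises held heart stress genes and heat shock genes. Nppa (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079, GRCm38) rose from 222 ± 121 to 3725 ± 2137 CPM (log2 fold change 4.07 ± 0.84, adjusted p = 0.0494). Ankrd1, a stretch-responsive cofactor of the sarcomere, rose from 374 ± 192 to 2705 ± 1517 CPM (2.85 ± 0.50, adjusted p = 0.0376). Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156), an inducible Hsp70 chaperone, rose from 2.15 ± 2.37 to 38.8 ± 13.8 CPM (4.14 ± 0.71, adjusted p = 0.0376). Cebpb (ENSMUSG00000056501, chromosome 2, 167688915 to 167690418) rose from 2.44 ± 1.49 to 39.5 ± 5.11 CPM (3.99 ± 0.75, adjusted p = 0.0376). Its transcript is GC-rich (67.2%, against a median of 50.4% in the tested genes).

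The fetal and hypertrophy list rose as a group: 4 of 17 tested members rose over all genes and 14 adjusted over the list alone (median 2.20, camera adjusted p = 7.9e-28, adjusted p = 0.0108 with an estimated correlation). Besides Nppa and Ankrd1 these were Rcan1, an inhibitor of calcineurin (2.99), and Xirp2, an actin-binding protein of the intercalated disc (2.59). Of 15 heat shock genes, 3 rose over all genes and 11 adjusted over the list alone (camera adjusted p = 3.77e-18, adjusted p = 0.0108 with an estimated correlation); these 3 were Hspa1a, its near-identical copy Hspa1b (3.90) and Hsp90aa1 (1.62). With an estimated correlation and the length covariate together neither list passed (adjusted p = 0.0854 for both). Other named rises were Aqp8, a water channel (3.52), Abra, an actin-binding protein (3.34), the clock-linked repressor Nfil3 (2.19) and the fibroblast marker Pi16 (1.33). The falls were Cers4, a ceramide synthase (-1.31), Prkab1, a subunit of AMP-activated kinase (-1.06), Nrp1, a co-receptor for VEGF and semaphorins (-1.04), Prr12 (-1.03), Ralgds (-0.96) and the ventricular transcription factor Irx4 (-0.86). Acta1 (4.14 ± 0.95, adjusted p = 0.076), Postn, a matrix protein of activated fibroblasts (3.46 ± 0.80, adjusted p = 0.076), Nppb (3.39 ± 0.84, adjusted p = 0.0968) and Myh7, the fetal myosin heavy chain (1.76 ± 0.53, adjusted p = 0.186), did not pass. All 38 extracellular matrix genes had positive fold changes, 12 past the threshold adjusted over the list alone and 0 over all genes (median 0.93, camera adjusted p = 2e-17, adjusted p = 0.185 with an estimated correlation). The calls did not survive every library: 0 genes were called without Sham replicate 1 or 2 or without AB_Implant replicate 1 or 3, 33 without Sham replicate 3 and 155 without AB_Implant replicate 2. Sample weights gave 505 calls, DESeq2 236 and the length covariate 679, with Acta1 (adjusted p = 0.0105), Postn (adjusted p = 0.0106), Nppb (adjusted p = 0.011) and Myh7 (adjusted p = 0.038) among them; 161 were called without the 3 libraries of the steepest slopes.

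**Figure D2:**
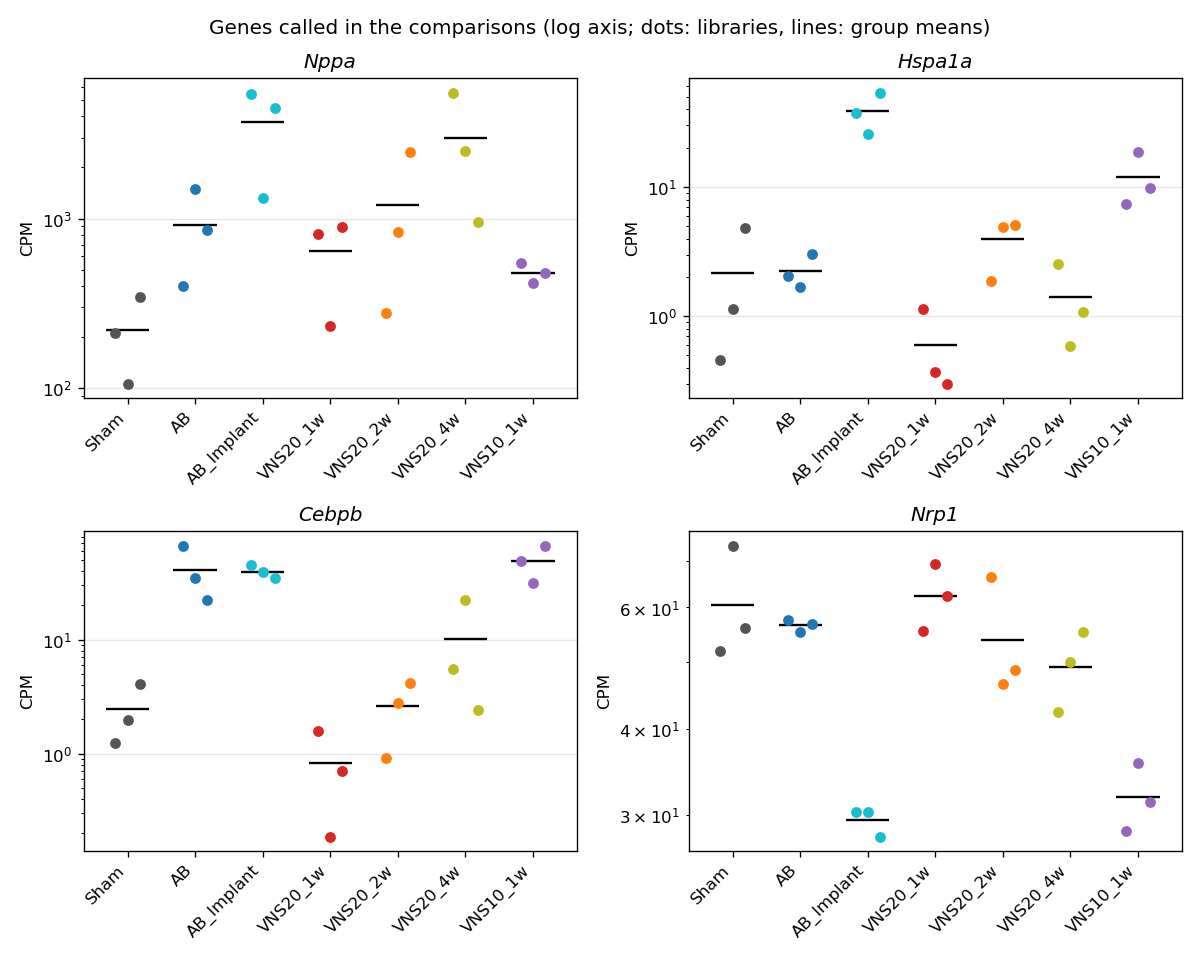
CPM (log axis) of Nppa, Hspa1a, Cebpb and Nrp1 in each library by group; dots are libraries and lines are group means. Mean Nppa is 3725 CPM in AB_Implant against 222 in Sham, and mean Cebpb is 0.824 CPM in VNS20_1w against 39.5 in AB_Implant.

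AB_Implant against AB asked what the inactive device added, and 0 genes were called by edgeR. By the naming rule the genes with the smallest p, none past the threshold, were Irx4 (28.7 ± 1.47 CPM in AB, 13.8 ± 1.74 in AB_Implant, log2 fold change -1.06 ± 0.17, adjusted p = 0.109), Hspa1a and Nrp1. Hspa1a was 2.26 ± 0.702 and 38.8 ± 13.8 CPM (4.08 ± 0.71, adjusted p = 0.117), and Nrp1 56.5 ± 1.21 and 29.5 ± 1.37 CPM (-0.94 ± 0.18, adjusted p = 0.121). No gene of the fixed set passed. Postn (2.22 ± 0.76, adjusted p = 0.403) and Nppa (2.02 ± 0.77, adjusted p = 0.46) had the largest fold changes. The other genes of the fixed set lay between -0.73 for Adrb1 and 1.00 for Acta1. Fetal and hypertrophy genes were higher in AB_Implant by list, with 7 of 17 past the threshold adjusted over the list alone and 0 over all genes (median 1.06, camera adjusted p = 2.69e-09, adjusted p = 0.40 with an estimated correlation). Heat shock genes were likewise higher, 5 of 15 adjusted over the list alone and 0 over all genes (camera adjusted p = 1.54e-08, adjusted p = 0.379 with an estimated correlation). At an unadjusted p under 0.05 there were 1099 genes, DESeq2 called 70, the length covariate 57, sample weights 11, and 3 were called without AB_Implant replicate 2. Without the 3 libraries of the steepest slopes 37 genes were called.

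All 4 stimulated groups held transcripts of genes known from the liver that the unstimulated hearts nearly lacked. Alb, serum albumin (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602, GRCm38), ranged from 9.18 to 76.6 CPM in the 12 stimulated libraries and from 0 to 1.18 CPM in the 9 others. Cyp3a11, a liver cytochrome P450 (ENSMUSG00000056035, chromosome 5, 145854426 to 145879964), ranged from 0.837 to 16.1 CPM and from 0 to 0.0686 CPM. Alb and Cyp3a11 were called in each of the 8 contrasts of a stimulated group with AB_Implant or AB. Of the genes called higher against AB_Implant, those with a mean under 0.1 CPM in the 9 unstimulated libraries were 18 of 22 in VNS20_1w, 13 of 16 in VNS20_2w, 22 of 30 in VNS20_4w and 12 of 13 in VNS10_1w. Further members, chosen after their values were seen, were Gc, the vitamin D binding protein (4.93 ± 1.34 CPM in 12 stimulated and 0.0327 ± 0.0653 in 9 other libraries), and Fabp1, the liver fatty acid binding protein (5.08 ± 3.47 and 0.00666 ± 0.02). Others were Apoa1, an HDL apolipoprotein (4.44 ± 3.11 and 0.0612 ± 0.0706), Kng1, kininogen (1.27 ± 0.340 and 0), and Ambp, a plasma protein precursor (1.45 ± 0.609 and 0). Cyp4a10 (5.16 ± 3.57 and 0.0486 ± 0.111 CPM) has near-identical copies, so its value may include their reads.

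**Figure D3:**
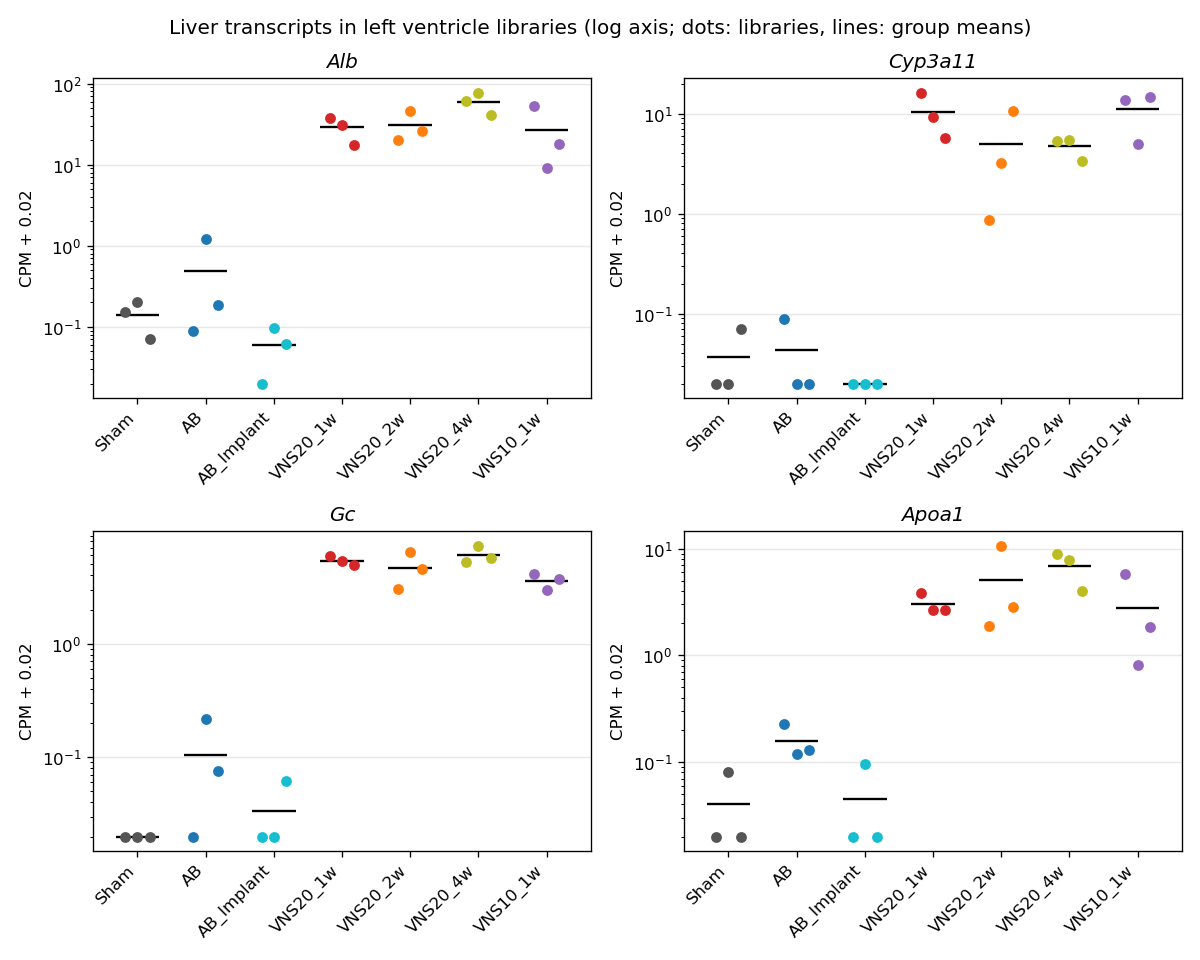
CPM plus 0.02 (log axis) of Alb, Cyp3a11, Gc and Apoa1 in each library by group; dots are libraries and lines are group means. For all 4 genes every one of the 12 stimulated libraries lies above every one of the 9 others; the lowest stimulated library for Alb is at 9.18 CPM and the highest other at 1.18.

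VNS20_1w against AB_Implant asked what 7 weeks of 20 min sessions changed with the device in place, and 56 genes were called, 22 higher and 34 lower. The falls included heat shock, immediate early and hypertrophy genes. Hspa1a fell from 38.8 ± 13.8 to 0.605 ± 0.463 CPM (log2 fold change -5.94 ± 0.81, adjusted p = 0.00118) and Cebpb from 39.5 ± 5.11 to 0.824 ± 0.704 CPM (-5.55 ± 0.85, adjusted p = 0.00453). Besides liver genes, Nrp1 (ENSMUSG00000025810, chromosome 8, 128358604 to 128503363) rose from 29.5 ± 1.37 to 62.4 ± 6.91 CPM (1.08 ± 0.18, adjusted p = 0.00735). Irx4 (ENSMUSG00000021604, chromosome 13, 73260479 to 73269608) rose from 13.8 ± 1.74 to 24.3 ± 4.12 CPM (0.82 ± 0.17, adjusted p = 0.042). Alb, as the CPM of the summed counts, was 795 times that of AB_Implant (95% counting interval 220 to 6571, 1269 against 2 counts), and Cyp3a11 was at least 193-fold higher (461 against 0 counts over the group).

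Of 15 heat shock genes, 4 fell over all genes and 9 adjusted over the list alone (camera adjusted p = 1.6e-20, adjusted p = 0.0138 with an estimated correlation and 0.0592 with the length covariate as well). They were Hspa1a, Hspa1b (-5.93), the Hsp110 chaperone Hsph1 (-1.69) and Hsp90aa1 (-1.68). Of 17 fetal and hypertrophy genes, 2 fell over all genes, Rcan1 (-3.08) and the actin crosslinker Flnc (-1.61), and 11 adjusted over the list alone (median -1.69, camera adjusted p = 1.1e-14, adjusted p = 0.0813 with an estimated correlation). Of 23 immediate early genes, 2 fell over all genes, the transcription factor Jund (-3.16) and the matricellular protein Ccn1 (-2.10), and 10 adjusted over the list alone (camera adjusted p = 7.79e-13, adjusted p = 0.0813 with an estimated correlation). Atf3, a transcription factor of the integrated stress response, fell too (-5.12 ± 1.07, adjusted p = 0.0396). All 38 extracellular matrix genes had negative fold changes, 20 past the threshold adjusted over the list alone and 0 over all genes (median -1.01, camera adjusted p = 7.06e-19, adjusted p = 0.281 with an estimated correlation). Other falls were Scand1 (-5.35), Abra (-3.44), the cell cycle inhibitor Cdkn1a (-3.31), the zinc finger gene Zfp771 (-3.26), Nfil3 (-2.37) and Srxn1, which repairs oxidised peroxiredoxins (-2.30). Many of these genes were high in AB_Implant, with AB nearer to VNS20_1w. Means in AB, AB_Implant and VNS20_1w were 2.26, 38.8 and 0.605 CPM for Hspa1a, 24.4, 151 and 17.8 for Rcan1, 71.9, 408 and 37.5 for Abra, and 13.5, 47.4 and 9.23 for Nfil3. Of the named falls only Cebpb, Jund, Scand1 and Zfp771 were also called against AB, and Nrp1 and Irx4 were at 56.5 and 28.7 CPM in AB. Cebpb, Jund, Scand1 and Zfp771 are all GC-rich (67.1% to 68.7%, against a median of 50.4% in the tested genes). Nppa (-2.54 ± 0.79, adjusted p = 0.239), Postn (-2.43 ± 0.76, adjusted p = 0.243), Acta1 (-2.20 ± 0.88, adjusted p = 0.421) and the muscarinic receptor gene Chrm2 (0.95 ± 1.04, adjusted p = 0.941), through which the vagus slows the heart, did not pass. The other genes of the fixed set lay between -1.97 for Timp1 and 0.36 for Myh6 (adjusted p at least 0.532). The count was 19, 101 and 12 without AB_Implant replicate 1, 2 and 3, and 32, 27 and 29 without VNS20_1w replicate 1, 2 and 3. It was 190 with DESeq2, 2066 with sample weights, 436 with the length covariate, 186 without the 3 libraries of the steepest slopes and 14 in a fit on the 2 groups alone.

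VNS20_2w against AB_Implant gave 21 calls, 16 higher and 5 lower. An implant week is given only for AB_Implant (week 1), so the time since implantation may differ between these groups. Alb was 708 times that of AB_Implant (interval 196 to 5856, 1335 against 2 counts). Cebpb fell from 39.5 ± 5.11 to 2.63 ± 1.64 CPM (-3.96 ± 0.76, adjusted p = 0.0385) and Mrfap1 from a mean of 52.0 to 22.5 CPM (-1.21 ± 0.23, adjusted p = 0.0385). Heat shock genes were lower by list, 5 of 15 adjusted over the list alone and 0 over all genes (camera adjusted p = 1.48e-08, adjusted p = 0.167 with an estimated correlation). Of 29 genes of the respiratory chain and citric acid cycle, 27 had positive fold changes, with 0 past the threshold on either count (median 0.35, camera adjusted p = 4.62e-05, adjusted p = 0.398 with an estimated correlation). Endothelial markers had positive fold changes in 9 of 10 cases, with 0 past the threshold on either count (median 0.45, camera adjusted p = 0.00671, adjusted p = 0.167 with an estimated correlation, fry adjusted p = 0.0134). Nppa (-1.64 ± 0.76, adjusted p = 0.938), Acta1 (-0.87 ± 0.84, adjusted p = 0.942) and Il1b, interleukin 1 beta (2.02 ± 1.04, adjusted p = 0.938), did not pass. The other genes of the fixed set lay between -2.13 for Postn and 0.85 for Timp1 (adjusted p at least 0.648). The count was 5 and 4 without AB_Implant replicate 1 and 3, and 9 without VNS20_2w replicate 2. It was 78 with DESeq2, 2241 with sample weights, 81 with the length covariate, 1 in a fit on the 2 groups alone and 1710 without the 3 libraries of the steepest slopes, where VNS20_2w kept 2 libraries of low slope.

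VNS20_4w against AB_Implant gave 39 calls, 30 higher and 9 lower. Here too the time since implantation may differ, since no implant week is given for VNS20_4w. Alb was 1552 times that of AB_Implant (interval 429 to 12824, 2068 against 2 counts). Irx4 rose from 13.8 ± 1.74 to 28.6 ± 5.37 CPM (1.06 ± 0.17, adjusted p = 0.00847) and Eml3, a microtubule-binding protein gene, from 8.73 ± 0.396 to 16 ± 1.36 CPM (0.87 ± 0.17, adjusted p = 0.0362). Hspa1a fell from 38.8 ± 13.8 to 1.41 ± 1.02 CPM (-4.79 ± 0.75, adjusted p = 0.00565). Irs2, an adaptor of the insulin receptor, fell from 11.7 ± 8.23 to 0.374 ± 0.107 CPM (-4.94 ± 0.98, adjusted p = 0.0341). Trib1 (-2.69), a pseudokinase that directs protein degradation, Cnksr3 (-2.18), which takes part in sodium channel regulation, and Tmem144 (-1.16) fell as well. None of these falls was called against AB, where the means were 2.26 CPM for Hspa1a, 2.11 for Irs2, 3.75 for Trib1 (12.8 in AB_Implant, 1.98 in VNS20_4w) and 6.52 for Cnksr3 (27.5 and 6.06), and Irx4 was at 28.7 CPM in AB. Of 15 heat shock genes 8 were lower adjusted over the list alone and 1 over all genes (camera adjusted p = 0.00119, adjusted p = 0.708 with an estimated correlation). Acta1 (0.14 ± 0.84, adjusted p = 0.911), Nppa (-0.32 ± 0.75, adjusted p = 0.771) and Col1a1 (0.10 ± 0.45, adjusted p = 0.879) did not pass. The other genes of the fixed set lay between -2.90 for Chrm2 and 1.15 for Il1b (adjusted p at least 0.173). The 2 groups did not overlap in length slope (-0.288 to -0.235 and 0.0315 to 0.235), and with the slope as a covariate 38 genes were called, 27 of them among the 39. Of the named genes, Eml3 (adjusted p = 0.057) and Tmem144 (adjusted p = 0.0714) did not pass with it. The count was 2, 14 and 25 without AB_Implant replicate 3, 1 and 2, and 18 and 19 without VNS20_4w replicate 2 and 3. It was 461 with DESeq2, 4977 with sample weights, 4058 in a fit on the 2 groups alone and 3807 without the 3 libraries of the steepest slopes.

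VNS10_1w against AB_Implant asked about the shorter daily session and gave 19 calls, 13 higher and 6 lower. Extracellular matrix genes fell as a group: 2 of 38 fell over all genes and 33 adjusted over the list alone (median -1.61, camera adjusted p = 4.09e-46, adjusted p = 0.029 with an estimated correlation). Col15a1, a basement membrane collagen, fell from 58.1 ± 25.4 to 14.1 ± 3.78 CPM (-2.04 ± 0.36, adjusted p = 0.0257) and Col16a1 from 13.9 ± 6.05 to 4.88 ± 0.274 CPM (-1.51 ± 0.27, adjusted p = 0.0264). Col6a1 (-1.29), Ccn1 (-2.0), the acute-phase protease inhibitor Serpina3n (-3.01) and the ciliary transport gene Ift122 (-1.31) fell as well, and none of these falls was called against AB. Fetal and hypertrophy genes were lower, 14 of 17 adjusted over the list alone and 0 over all genes (median -1.56, camera adjusted p = 8.02e-18, adjusted p = 0.029 with an estimated correlation). Lists of cell cycle genes (6 of 20 adjusted over the list alone, 0 over all genes) and inflammatory genes (2 of 19 and 0) also fell by camera (adjusted p = 2.84e-10 for both, and adjusted p = 0.029 with an estimated correlation). Fibroblast markers fell too (4 of 10 adjusted over the list alone, 0 over all genes, median -0.51, camera adjusted p = 9.81e-07, adjusted p = 0.0365 with an estimated correlation). Alb was 591 times that of AB_Implant (interval 163 to 4887, 1104 against 2 counts) and Cyp3a11 was at least 176-fold higher. Col1a1 (-2.03 ± 0.47, adjusted p = 0.127), Col3a1 (-2.17 ± 0.50, adjusted p = 0.128), Postn (-3.18 ± 0.79, adjusted p = 0.175) and Nppa (-2.96 ± 0.80, adjusted p = 0.235) did not pass. The other genes of the fixed set lay between -2.79 for Timp1 and 0.62 for Adrb1 (adjusted p at least 0.403). The count was 5, 59 and 4 without AB_Implant replicate 1, 2 and 3, and 6, 12 and 8 without VNS10_1w replicate 1, 2 and 3. It was 91 with DESeq2, 2024 with sample weights, 167 with the length covariate, 44 without the 3 libraries of the steepest slopes and 2 in a fit on the 2 groups alone, and with an estimated correlation and the length covariate together 0 lists were called.

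Against AB, banded mice without a device, VNS20_1w had 35 calls (15 higher, 20 lower), VNS20_2w 13 (10 and 3), VNS20_4w 18 (16 and 2) and VNS10_1w 6 (6 and 0). Alb, by the CPM of summed counts, was 81.3, 72.4, 159 and 60.4 times that of AB in these groups (counting intervals 49.9 to 143, 44.4 to 127, 97.5 to 278 and 37.0 to 106). Of the 16 Alb counts of AB, 12 were in AB replicate 2. In VNS20_1w, Cebpb fell from 41.0 ± 22.4 to 0.824 ± 0.704 CPM (-5.61 ± 0.85, adjusted p = 0.00511). Hnrnpa0, an RNA-binding protein gene, fell from 36.8 ± 4.69 to 3.35 ± 1.21 CPM (-3.44 ± 0.42, adjusted p = 0.000682), and Jund from 94.3 ± 19.7 to 7.98 ± 5.88 CPM (-3.56 ± 0.61, adjusted p = 0.014). Nkx2-5, a core cardiac transcription factor, fell from 51.9 ± 8.26 to 8.38 ± 3.24 CPM (-2.63 ± 0.46, adjusted p = 0.017). Scand1 (-6.08), the neurotrophic factor Nrtn (-3.75) and Zfp771 (-3.70) fell as well, and so did Ccdc85b, from 29.6 ± 7.31 to 3.01 ± 1.78 CPM. Of these 8 genes 6 are GC-rich (67.1% to 72.8%), and AB replicate 1 stood apart in GC slope (0.430 log2 CPM per 10 points, others -0.241 to 0.167). With the GC and length offset Nrtn (log2 fold change -1.61) and Zfp771 (-2.13) did not pass. In VNS20_2w, Cebpb (-4.01 ± 0.76, adjusted p = 0.0488) and Hnrnpa0 (-2.13 ± 0.39, adjusted p = 0.0381) fell. No gene of the fixed set passed in any of the 4 groups. In VNS20_2w, VNS20_4w and VNS10_1w they lay between -0.92 (Adrb1) and 2.80 (Il1b), -2.48 (Chrm2) and 1.92 (Il1b), and -1.91 (Timp1) and 1.27 (Myh7) in this order. Nppa was at 1.71 ± 0.77 in VNS20_4w (adjusted p = 0.753). Mean Nppa was 916 CPM in AB, 642 in VNS20_1w, 1198 in VNS20_2w, 2988 in VNS20_4w and 480 in VNS10_1w. Matrix genes were lower in VNS10_1w, 7 of 38 adjusted over the list alone and 0 over all genes (median -0.85, camera adjusted p = 2.15e-13, adjusted p = 0.42 with an estimated correlation). Neutrophil markers were higher in VNS20_1w, 4 of 4 adjusted over the list alone and 0 over all genes (median 3.25, camera adjusted p = 0.000177, adjusted p = 0.628 with an estimated correlation). The VNS20_1w libraries differed widely (S100a8 from 0.758 to 12.0 CPM), and AB was low, with mean S100a8 of 0.579 CPM against 3.79 in Sham. In VNS20_2w 3 of 4 neutrophil markers were higher adjusted over the list alone and 0 over all genes (median 3.39, camera adjusted p = 6.19e-07, adjusted p = 0.133 with an estimated correlation). Without AB replicate 1, 2 or 3 the counts were 11, 15 and 20 for VNS20_1w, 3, 7 and 3 for VNS20_2w, 2, 7 and 2 for VNS20_4w, and 3, 6 and 3 for VNS10_1w. Without stimulated replicate 1, 2 or 3 they were 19, 10 and 15 for VNS20_1w, 12, 8 and 3 for VNS20_2w, 13, 13 and 11 for VNS20_4w, and 6, 11 and 4 for VNS10_1w. Fits on the 2 groups alone gave 10, 0, 17 and 2 calls, DESeq2 86, 54, 37 and 25, sample weights 42, 5, 5 and 15, and the length covariate 151, 81, 21 and 24.

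Stimulation in general was tested with the 12 stimulated against the 6 unstimulated banded libraries, and 53 genes were called, 34 higher and 19 lower. Of the rises, 27 had a mean under 0.1 CPM in the 9 unstimulated libraries. Ehhadh (ENSMUSG00000022853, chromosome 16, 21761287 to 21787807), a peroxisomal enzyme of fatty acid oxidation that heart tissue also expresses, rose from 4.78 ± 0.905 (n = 6) to 13.6 ± 5.30 CPM (n = 12; log2 fold change 1.49 ± 0.26, adjusted p = 0.00802). Sham, outside this contrast, was at 10.6 ± 4.29 CPM (n = 3). Hspa1a fell (-1.89 ± 0.40, adjusted p = 0.0398), but its mean was 38.8 CPM in AB_Implant and 2.26 in AB, and VNS20_2w (3.97) and VNS10_1w (12.0) lay above AB. Among the other falls were Jund (-1.52 ± 0.32, adjusted p = 0.0382) and Ccn1 (-1.05 ± 0.21, adjusted p = 0.0245). The mitotic kinase gene Aurka (-1.46 ± 0.29, adjusted p = 0.0245) and Jph2, which ties the calcium store to the cell membrane (-0.64 ± 0.13, adjusted p = 0.0375), fell as well. Some of these falls were not shared by all groups. Mean Jph2 was 148 CPM in AB, 156 in AB_Implant, 145 in VNS10_1w and 79.3 to 92.4 in the 20 min groups. Mean Jund was 62.8 CPM in VNS10_1w and 55.6 in VNS20_4w (71.8 in AB_Implant), and Ccn1 was high in AB_Implant (122 CPM, against 41.0 in AB and 28.5 to 43.8 in the stimulated groups). Extracellular matrix genes were lower in 37 of 38 cases, 5 past the threshold adjusted over the list alone and 0 over all genes (median -0.56, camera adjusted p = 3.07e-17, adjusted p = 0.437 with an estimated correlation). Nppa (-0.85 ± 0.44, adjusted p = 0.986), Postn (-1.20 ± 0.43, adjusted p = 0.744), Acta1 (-0.87 ± 0.50, adjusted p = 0.986) and Chrm2 (-0.09 ± 0.63, adjusted p = 0.997) did not pass. The count stayed between 36 and 58 with any 1 library left out, and was 112 with the length covariate, 83 with DESeq2, 443 with sample weights, 4 among genes with a mean of at least 5 CPM and 2120 without the 3 libraries of the steepest slopes.

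VNS20_1w against VNS10_1w compared session lengths at the same start and duration, and 12 genes were called, 2 higher and 10 lower with 20 min. Cebpb was 0.824 ± 0.704 CPM with 20 min and 48.7 ± 17.4 with 10 min (-5.86 ± 0.86, adjusted p = 0.00851). Hnrnpa0 was 3.35 ± 1.21 and 34.4 ± 3.20 CPM (-3.34 ± 0.42, adjusted p = 0.00271) and Hspa1a 0.605 ± 0.463 and 12.0 ± 5.98 CPM (-4.25 ± 0.77, adjusted p = 0.0379). Nrp1 was higher with 20 min (62.4 ± 6.91 and 31.9 ± 3.66 CPM, 0.97 ± 0.18, adjusted p = 0.0379). The genes of the fixed set lay between -0.96 for Adrb1 and 1.30 for Col3a1, and none passed (adjusted p at least 0.788). Neutrophil markers were higher with 20 min, 4 of 4 adjusted over the list alone and 0 over all genes (median 3.31, camera adjusted p = 2.65e-08, adjusted p = 0.0411 with an estimated correlation). The VNS20_1w libraries differed widely, with list means of 0.225, 3.21 and 1.37 log2 units in replicates 1, 2 and 3 (-0.399 to 0.154 in VNS10_1w). Inflammatory genes were higher in 17 of 19 cases, 1 past the threshold adjusted over the list alone and 0 over all genes (median 0.85, camera adjusted p = 1.76e-09, adjusted p = 0.0411 with an estimated correlation). Heat shock genes were lower, 6 of 15 adjusted over the list alone and 1 over all genes (camera adjusted p = 1.32e-12, adjusted p = 0.0411 with an estimated correlation). The count was 0 without VNS20_1w replicate 2 or 3 and 6, 4 and 5 without VNS10_1w replicate 1, 2 and 3. It was 0 in a fit on the 2 groups alone, 3 without the 3 libraries of the steepest slopes, 56 with DESeq2, 1994 with sample weights and 111 with the length covariate. Of the lists, fry called 0, and none passed with an estimated correlation and the length covariate together.

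The start of stimulation at week 1, 2 or 4 was tested with an F test over VNS20_1w, VNS20_2w and VNS20_4w, in which start and number of treated weeks change together. The time since implantation may change with them, since no implant week is given for these groups. By edgeR 0 genes were called, with 1119 at an unadjusted p under 0.05 and 35 called by DESeq2. By the naming rule the genes with the smallest p, none past the threshold (adjusted p = 0.119 for each), were Hnrnpa0 (3.35 ± 1.21, 8.46 ± 2.40 and 20.2 ± 8.81 CPM), Scand1 (0.546 ± 0.443, 1.75 ± 1.51 and 23.6 ± 17 CPM) and Zfp771 (1.79 ± 0.956, 3.30 ± 2.16 and 23.3 ± 13.9 CPM). Scand1 and Zfp771 are GC-rich (68.4% and 68.7%), and Hnrnpa0 less so (55.4%). Mean Acta1 was 1439 ± 1247, 3618 ± 2862 and 7280 ± 4427 CPM and mean Nppa 642 ± 358, 1198 ± 1147 and 2988 ± 2312 CPM (adjusted p = 0.517 for both). Without VNS20_2w replicate 1 11 genes were called, without VNS20_4w replicate 3 there were 3, and the length covariate gave 16. Sample weights gave 2519.

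The banding score placed the groups on a scale whose ends were set by Sham and AB (mean -1.33 ± 0.486 and 0.752 ± 0.432 log2 units). The genes were chosen by their p in these same Sham and AB libraries, which by itself pushes the ends apart. Groups not used for the choice would tend to lie between them, so a place between the ends does not measure the response to banding. AB_Implant lay at 0.222 ± 0.264, VNS20_1w at -0.189 ± 0.474, VNS20_2w at 0.138 ± 0.637, VNS20_4w at 0.684 ± 0.346 and VNS10_1w at -0.0875 ± 0.168 (n = 3 each). Against AB_Implant the differences were -0.41 (two-sided exact permutation p = 0.3), -0.08 (p = 1), 0.46 (p = 0.2) and -0.31 (p = 0.3), where 3 against 3 libraries cannot give less than 0.1. The 12 stimulated libraries together differed from AB_Implant by -0.09 (two-sided exact permutation p = 0.798 over 455 splits). The 100 genes higher in AB were lower in VNS20_1w than in AB_Implant as a set (median -0.35, camera p = 8.66e-10, p = 0.115 with an estimated correlation, fry p = 0.0668), and VNS10_1w had the same direction (median -0.23, camera p = 9e-05, p = 0.305 with an estimated correlation). VNS20_4w went the other way, with the genes higher in AB up (median 0.28, camera p = 0.0136, p = 0.511 with an estimated correlation) and the 100 lower genes down (median -0.32, camera p = 0.00138, p = 0.365 with an estimated correlation). Left-out libraries turned the sign of the VNS20_2w difference (0.28 without VNS20_2w replicate 1, 0.05 without Sham replicate 2 or AB_Implant replicate 1, 0.02 without AB replicate 3, 0.01 without Sham replicate 1). They also turned that of the 12 libraries (0.09 without AB replicate 3, 0.04 without AB_Implant replicate 1, 0.03 without Sham replicate 1).

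**Figure D4:**
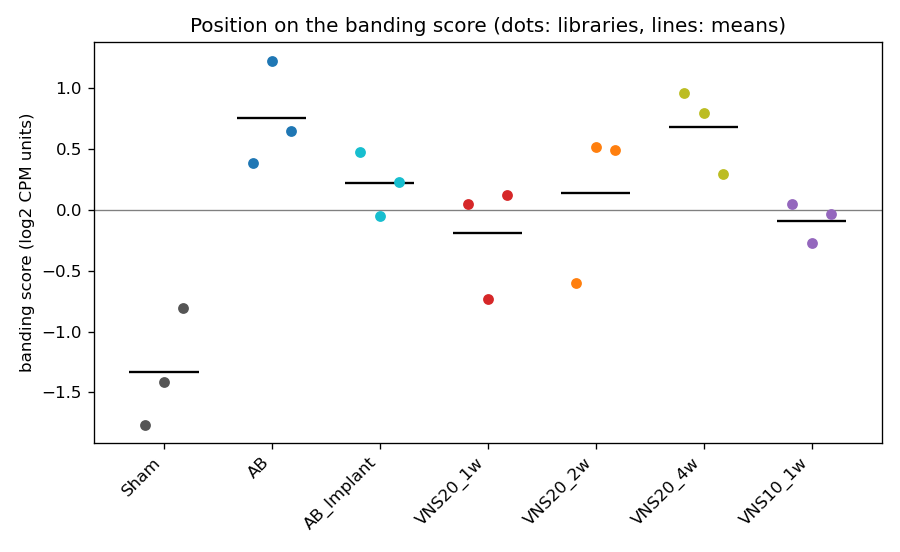
Banding score of each library by group in log2 CPM units; dots are libraries and lines are group means, and genes were chosen from Sham and AB. AB_Implant and the 4 stimulated groups have means between -0.189 and 0.684, inside the ends of -1.33 (Sham) and 0.752 (AB), which the choice of genes itself pushes apart.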

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

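The tests of a GC or length trend and of session length below were chosen after the result was seen. The test of GC-rich stretches was fixed before its own values, but for genes already called.

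The 20 and 10 min groups were compared directly, at the same start and duration, and 12 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; this difference between groups of 1 contrast brings them here. Lower with 20 min were Cebpb (log2 fold change -5.86), Scand1 (-5.62), Gm9887 (-5.55), Nudt3 (-4.97), Hspa1a (-4.25), Hnrnpa0 (-3.34), Eid2b (-3.12), Pabpn1 (-3), BC029722 (-1.84) and Mrfap1 (-1.66). Higher with 20 min were C3ar1, a complement receptor of myeloid cells (2.01), and Nrp1 (0.97). Genes outside the naming rule are named here since all 12 are listed.

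For the 10 lower genes, a smooth trend of counts with GC content or length was weighed first: 9 of the 10 were still called with an offset that removes it (median log2 fold change -3.80 before and -3.79 after), which argues against that trend as the whole cause. Gm9887 was the exception (-5.55 ± 0.84 before, -4.25 ± 1.20 after, adjusted p = 0.201), its fold smaller and its SE larger with the offset. A loss of fragments at very GC-rich stretches could not be excluded: among genes of like GC content and level, the richest 200-base window of these genes stood at a median percentile of 71.4 (range 0 to 98.6), between the bounds of 60 and 75 set for the test, and at 76.7 in the 8 genes with at least 20 matched genes, a limit chosen after the values were seen (Gm9887 had 2 and Scand1 15). Session length stays open as well, since 3 of the 10 genes had an AB mean at least 4 times the Sham mean, a difference without any stimulation, and banding can also raise a gene that stimulation lowers. GC-rich stretches and session length cannot be told apart with 3 mice a group and no batch in the labels, and 0 genes were called without VNS20_1w replicate 2 or 3.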

How the results depend on the processing

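The counts of called genes depended on the settings, while named genes past the threshold kept their direction. The naming rule favours this, since the largest rises and falls had to come from groups that do not overlap. Among 261 pairs of a named gene and a comparison, none changed sign while past the threshold in either fit (182 sign changes had neither fit past it). In all, 87 pairs were past it, 12 of them under every other setting that tested the gene and 19 with every single library left out. The 12 were Alb in VNS20_1w, VNS20_2w and VNS20_4w against AB_Implant, Cyp3a11, Hspa1a, Hspa1b and Cebpb in VNS20_1w and Hspa1a in VNS20_4w against AB_Implant, Cebpb and Hnrnpa0 in VNS20_1w against AB, and Alb and Cyp3a11 in the 4 groups together. Cyp3a11 lay under the filter of a mean of at least 5 CPM, so that setting did not test it. Of the 174 pairs not past it, 29 passed in at least 1 setting. Of the counts of called genes under other settings, 89 moved by more than 1.5 times and 51 did not. The cause of the differences was not tested. The stricter filter tests fewer genes, a fit on the compared groups has fewer libraries, and the 3 steep libraries belong to VNS20_1w, VNS20_2w and VNS10_1w, while counts also moved between groups that lost none. The length covariate, the offset and the fit without 3 libraries were chosen after seeing the data.

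Counts are given in 1 order: AB against Sham, AB_Implant against Sham, AB_Implant against AB, VNS20_1w, VNS20_2w, VNS20_4w and VNS10_1w against AB_Implant, the same groups against AB, the 4 stimulated groups together, VNS20_1w against VNS10_1w, and the F test over start weeks. As reported they were 0, 34, 0, 56, 21, 39, 19, 35, 13, 18, 6, 53, 12 and 0. Without a filter they were 0, 26, 0, 74, 30, 44, 21, 34, 14, 21, 10, 80, 15 and 0. With a mean of at least 5 CPM they were 0, 39, 1, 24, 1, 3, 1, 13, 1, 1, 1, 4, 4 and 0. With DESeq2 size factors they were 0, 28, 0, 55, 29, 35, 20, 35, 13, 18, 10, 53, 12 and 0. Fits on the compared groups alone gave 1, 33, 7, 14, 1, 4058, 2, 10, 0, 17, 2, 50, 0 and 0. Sample weights gave 0, 505, 11, 2066, 2241, 4977, 2024, 42, 5, 5, 15, 443, 1994 and 2519. DESeq2 gave 11, 236, 70, 190, 78, 461, 91, 86, 54, 37, 25, 83, 56 and 35. The length covariate gave 4, 679, 57, 436, 81, 38, 167, 151, 81, 21, 24, 112, 111 and 16. The GC and length offset gave 0, 140, 4, 131, 56, 76, 30, 37, 15, 18, 9, 61, 33 and 0. Without the 3 libraries of the steepest length slope the counts were 3, 161, 37, 186, 1710, 3807, 44, 33, 20, 22, 11, 2120, 3 and 0.

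The replicate number as a block gave 0, 0, 0, 31, 9, 18, 7, 13, 5, 8, 4, 36, 6 and 0 called genes. The labels tie no number to a litter, batch or day. Of 63 pairs of libraries with the same number, 17 had correlated deviations above 0.1 (median r over genes -0.05), and 7 of 21 libraries were closest to one with their own number, so the numbers were not taken to pair the mice. No libraries were duplicates.

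With each library left out in turn, the counts in the same order ran from 0 to 7, 0 to 155, 0 to 3, 12 to 101, 4 to 19, 2 to 42, 4 to 59, 10 to 20, 3 to 12, 2 to 13, 3 to 11, 36 to 58, 0 to 12 and 0 to 11. A group then held 2 libraries and shared the spread of all groups.

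Of 28 lists, camera called 10, 15, 8, 8, 13, 6, 14, 7, 5, 12, 9, 12 and 13 in the contrasts in this order, and 0, 2, 0, 1, 0, 0, 5, 0, 0, 0, 0, 0 and 3 with an estimated correlation. The length covariate gave 7, 15, 10, 9, 15, 5, 15, 7, 5, 6, 13, 11 and 14 with the preset correlation and 0 in every contrast with an estimated one. The block gave 10, 15, 8, 8, 14, 6, 14, 7, 6, 12, 9, 12 and 13.

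The score differences from AB_Implant kept their sign in VNS20_1w, VNS20_4w and VNS10_1w under every setting tried. Without the 3 libraries of the steepest slope they reversed to 0.28 in VNS20_2w and to 0.14 for the 12 stimulated libraries. With each library left out they ran from -0.57 to -0.14, -0.27 to 0.28, 0.15 to 0.66 and -0.50 to -0.06 in VNS20_1w, VNS20_2w, VNS20_4w and VNS10_1w, and from -0.22 to 0.0898 for the 12. With the length slope removed, a setting chosen after seeing the data, they were -0.46, -0.17, 0.22 and -0.34 in these groups. For the 12 the difference was then -0.19. As reported, VNS20_4w was at 0.46 and the 12 at -0.09. The p-values say nothing of stability, as 3 against 3 libraries cannot pass the threshold.

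Other pseudocounts bear on the score alone, since the count test uses none. Depth limited the low genes, since 0 counts in a group allow up to 3.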

Other observations

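The test of a dose relation for the liver transcripts, and the settings built on the length slope, were chosen after the results were seen. The tests of liver and kidney RNA, of cell shares and of length bias were fixed before their own values, but for patterns already seen in these data. The remaining tests below were not chosen after their results.

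Of 3 metabolic lists, fatty acid oxidation and respiratory chain pointed up in stimulated groups relative to AB_Implant without any single member past the threshold over all genes, and only with the preset correlation. The first passed in 2 of the 4 groups, and glycolysis passed in VNS20_2w alone (14 of 18 positive fold changes, camera adjusted p = 0.0111, adjusted p = 0.426 with an estimated correlation). In VNS10_1w, 29 of 30 genes of fatty acid oxidation had positive fold changes (median 0.36, camera adjusted p = 9.81e-07, adjusted p = 0.208 with an estimated correlation), as did 26 of 29 genes of the respiratory chain and citric acid cycle (median 0.27, camera adjusted p = 0.000402, adjusted p = 0.487 with an estimated correlation). In VNS20_2w, 28 of 30 fatty acid oxidation genes had positive fold changes (median 0.29, camera adjusted p = 0.000375, adjusted p = 0.395 with an estimated correlation). In VNS20_1w it was 25 of 30 (camera adjusted p = 0.145) and in VNS20_4w 21 of 30 (camera adjusted p = 0.0717), and for the respiratory chain list 26 of 29 (camera adjusted p = 0.0145) and 23 of 29 (camera adjusted p = 0.00239, and 0.436 with the length covariate). Mitochondrial genes took 34.4% to 44.4% of the counts in AB_Implant and 36.4% to 55.3% in the stimulated libraries (49.6% to 52.7% in VNS20_4w). They took 45.7% to 49.99% in AB and 42.1% to 48.5% in Sham, so AB_Implant had the lowest range of the unstimulated groups. The range of AB lay within that of the stimulated libraries. Among these, the 3 with a length slope above 0.3 had 36.4% to 39.7% and the others 48.3% to 55.3%. In AB_Implant against Sham the fatty acid oxidation list had 3 of 30 positive fold changes (median -0.30, camera adjusted p = 0.000235, adjusted p = 0.332 with an estimated correlation). The circadian clock list in VNS20_4w against AB_Implant had 6 of 18 members past the threshold adjusted over the list alone, 3 higher and 3 lower, and 0 over all genes (median -0.88, camera adjusted p = 0.171).

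Immune lists had higher values with the longer session. With 20 min against 10 min from week 1, 11 of 12 macrophage and monocyte markers had positive fold changes, 0 past the threshold on either count (median 0.69, camera adjusted p = 3.32e-07, adjusted p = 0.0886 with an estimated correlation). The interferon response list had 23 of 24 positive fold changes, 0 past the threshold (median 0.52, camera adjusted p = 9.97e-06, adjusted p = 0.231 with an estimated correlation). In VNS10_1w against AB_Implant, 1 of 4 neutrophil markers was lower adjusted over the list alone and 0 over all genes (median -1.69, camera adjusted p = 0.000376, adjusted p = 0.157 with an estimated correlation). In AB_Implant against Sham, smooth muscle and pericyte markers were lower in 8 of 10 cases, 2 adjusted over the list alone and 0 over all genes (median -0.63, camera adjusted p = 0.00839, adjusted p = 0.0737 with an estimated correlation).

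Liver transcripts appeared in all 12 stimulated libraries. Kidney RNA was argued against, since 0% of 15 kidney genes had 10 or more counts and a 5-fold higher mean in the 12 stimulated libraries. Of 24 liver genes, none among the called genes, 75% (18) had a 5-fold higher mean, short of the 80% set for RNA of liver origin. Liver genes called as rising, such as Alb, were left out of this list, which can lower the share. The shortfall is therefore no argument against liver RNA. The other 6 of the 24 were 1.75 to 4.27 times higher, and Ahsg, Itih4 and Cyp2e1 were also at 1 CPM or more in the 9 other hearts. The summed liver genes lay at 21.4 ± 4.14 CPM in VNS20_1w, 29.9 ± 13 in VNS20_2w, 43.7 ± 4.79 in VNS20_4w and 18 ± 4.47 in VNS10_1w. They lay at 6.83 to 9.89 in the unstimulated groups, although AB replicate 2 at 13.32 lay above VNS10_1w replicate 2 at 12.96. With a ratio of 2.04 for 4 against 7 weeks of 20 min, this sum did not grow with the weeks of stimulation. Single genes went both ways. Cyp3a11 (10.4 CPM with 7 weeks, 4.91 with 6, 4.70 with 4) and Cyp2c29 (8.97, 4.99 and 0.866) were higher with 7 weeks than with 4. Alb (28.8, 30.7 and 59.5) and Apoa1 (3.01, 5.10 and 6.86) were lower with 7 weeks than with 4. Liver RNA carried over in handling that the stimulated animals shared, and expression in the heart under stimulation, may each account for the liver transcripts. They cannot be told apart, since the 4 stimulated groups share both.

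The axis of transcript length was weighed against differing shares of cell types. Within 71 genes of cardiomyocyte, calcium handling and respiratory chain lists, the length slope of the libraries followed that of the other genes (n = 21, r = 0.925, Spearman correlation 0.908, permutation p = 1e-05 for both, the smallest that 100000 permutations can give; r = 0.901 without the 2 farthest libraries), which argues against cell shares as the whole cause. Within 57 genes of matrix, fibroblast and smooth muscle lists it did so too (r = 0.955, Spearman correlation 0.96, permutation p = 1e-05 for both; r = 0.935 without the 2 farthest), as a length bias of library preparation or RNA integrity would need. Such a bias may therefore underlie the axis, a hypothesis tested on the same data. With the slope as a covariate the common biological coefficient of variation was 0.198 in place of 0.36.

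For contrasts of 3 against 3 libraries there are 10 splits of the 6, too few for a share under 0.05. AB against Sham and AB_Implant against AB called 0 genes, so all 10 splits called as many, with 1 and 0 as the highest of the others. In the other 10 contrasts the real split alone, 1 of 10, called as many. AB_Implant against Sham called 34 (highest other 0). Against AB_Implant, VNS20_1w called 56 (highest other 0), VNS20_2w 21 (1), VNS20_4w 39 (1) and VNS10_1w 19 (0). Against AB the groups called 35, 13, 18 and 6 (highest other 0 each), and VNS20_1w against VNS10_1w called 12 (highest other 0).

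For the 4 stimulated groups against AB and AB_Implant, 5 of 100 splits called as many as the real 53, and the highest of the others called 4177, so chance is not excluded for that count. The 4 other splits as large had length slopes that differed between their sides by 0.256 or more, against 0.0846 in the real split and a median of 0.0826 over all splits, and the largest put the 3 libraries of steepest slope on 1 side, which points to this structure of the libraries. For the F test over start weeks all 100 splits called at least the real 0, 13 others called at least 1 gene and the highest called 4388, with 2 of the steep libraries in 1 group.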
